A study of Mus musculus with 3 samples.

How the data were processed

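Gene expression was measured in 3 mammary tumours of WAP-SVT/t transgenic mice, which per the labels make the T and t antigens of simian virus 40 in mammary epithelial cells. Per the labels' protocols, total RNA was extracted with RNAzol and transcribed into biotinylated cRNA, and 1 array was hybridised per tumour. The deposited table held 1 intensity per probe set and tumour on a linear scale, as whole numbers with no negative value. How the authors summarised probes into these intensities, subtracted background or scaled the arrays, and which software they used, was not given in the sources used here, so the normalization of the deposited values stays unknown. The linear scale was inferred from the values. No detection call was used here.

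The table held 22690 probe sets, of which 64 were controls and 22626 were used. Over these the median intensity was 111, 120 and 114 in tumours 1, 2 and 3, the quartiles were 19 and 406, 21 and 438, and 21 and 413, and the highest value was 11344, 11659 and 10789. Intensities of 0 occurred in 81, 46 and 79 probe sets. Genes were named from a table of the array platform's annotation, which gave 1 gene for 20380 probe sets and several genes for 691. Another 1555 probe sets were not listed there and stayed unnamed. Gene IDs of 20351 probe sets matched the RefSeq gene table of assembly GRCm38.p6, and 0 symbols had to be updated. Probe sets with several genes named none. This gave 12393 genes, 4956 of them with several probe sets. Since no genome build is named for the array table, no coordinates are given.

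All 3 samples form 1 group with no control sample, and the group's tumours are called tumour 1, 2 and 3 in accession order. No test between groups exists in this design and none was run. The comparisons describe differences between tumours. These were the correlation across genes, counts of genes at least 2-fold apart, the range over the tumours, the behaviour of gene lists and the agreement of probe sets of the same gene. With 1 array per tumour, a difference may include array and preparation effects, and only the number of arrays can be given as the limit of precision.

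These settings were fixed before the data were examined. An offset of 50 was added to each intensity before log2. Arrays were to be used as deposited if their 2% trimmed means agreed within 5%, and quantile normalized otherwise. The highest trimmed mean exceeded the lowest by 5.38% (328, 343 and 345 in tumours 1, 2 and 3), so the arrays were quantile normalized over all probe sets except controls. The rule did not say whether agreement was meant between extremes or from the mean, and measured from the mean of the arrays each would have passed, so the values as deposited are the first alternative. Before normalization the array medians deviated by -0.04, 0.04 and -0.01 (log2) from their mean. A gene took its probe set with the highest mean level. The low-signal filter kept genes whose mean reached the median of all probe sets, a log2 value of 7.40 or an intensity of 119, and 6952 genes passed. A gene counted as measured in a list when it passed this filter, a reading chosen once the values were seen.

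The fixed lists numbered 22, with 420 genes, of which 394 were on the array and 270 passed the filter. They covered milk and lactation, luminal and basal epithelium, DNA replication and E2F targets, mitosis, p53 targets, neuroendocrine genes, imprinted genes, adipocyte, muscle, fibroblast and matrix, endothelium, macrophage, T and NK cell, B and plasma cell, neutrophil, erythroid, interferon and antigen presentation, hypoxia and glycolysis, immediate early, X and Y transcripts, and ribosomal proteins. The pattern that matched ribosomal symbols was written with the symbols in view. For each of the 15 lists with at least 5 genes past the filter, the median range over the tumours and the median deviation of each tumour from the mean of the tumours (the shift) were ranked among 10000 random lists of the same size drawn from the same deciles of mean level. Genes of a list are not independent, so a percentile describes these arrays and is no test.

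Named genes followed a fixed rule. For each tumour these were the 5 genes with the widest gap above and the 5 with the widest gap below both others, 30 in all. In each ranked list they were the 2 members with the widest and the 1 with the narrowest range, and in a list with fewer than 5 genes past the filter all those members. A further 17 genes were named beforehand, 1 of which was not analysed here. Members added as examples for the interferon list and the p53 targets (Ifit1, Gbp2, Mx1 and Mdm2), and the exceptions among imprinted and milk genes (Plagl1, Csn1s1 and Csn1s2a) and the dim basal keratins Krt5 and Krt17, were chosen after their values were seen. The imprinted genes below the floor and the adipocyte gene Adipoq were also named after their values were seen.

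The calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. They were tested on simulated data with the levels of the 6952 genes and a noise SD of 0.31 per array, taken from the disagreement of probe sets. Of 100 genes planted 4-fold higher in 1 array 95 were called at least 2-fold above both others, as were 100 of 100 planted 8-fold higher and 27 of 6732 unplanted genes. The simulated noise had 1 SD at every level and left out variation that probe sets of the same array share, such as labelling. These shares are therefore no error rates of the real counts. A planted list of 20 genes 2-fold higher reached the top percentile, and 9 of 120 shifts of random lists fell outside the central 95%.

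Besides these settings the results were computed with the values as deposited, with subtraction of each array's median and with offsets of 16 and 150. Further alternatives were no low-signal filter, a filter at the 75th percentile, the mean of a gene's probe sets and leaving out suffixed probe sets. A suffixed probe set has the letter a, f, g, i, r, s or x before the ending of its ID. Not every such letter marks cross-hybridization to other genes. The last alternatives were unmatched random lists, thresholds of 1.5-fold and 4-fold, and leaving out each tumour in turn. Control probe sets stayed out of all gene results. Human tumours and further mouse tumours named in the design text were not analysed here.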

Results

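The data set held 1 array for each of 3 mammary tumours from female NMRI mice that carry the WAP-SVT/t transgene. In these mice the promoter of the milk protein gene Wap directs the large T and small t antigens of simian virus 40, viral proteins that inactivate cellular growth control, to the mammary epithelium. Total RNA was converted to biotin-labelled cRNA and hybridised to a 1-colour mouse array, and the deposited table gave 1 intensity per probe set and tumour. The median intensity was 111 in tumour 1, 120 in tumour 2 and 114 in tumour 3. Tumours 1 and 2 shared the leading number of their titles and tumour 3 carried another, and what that number stands for was not given in the sources used here. A second title number (3, 5 and 9) differed in every tumour, and its meaning was not given either. Whether tumours 1 and 2 came from 1 mouse stays unknown, so the values behind an SD may not be independent. The design text named 6 mouse and 24 human tumours and asked how alike tumours were in gene expression, between species and among themselves. Only the 3 mouse tumours were analysed here, with no normal gland beside them, so the comparison was between tumours. With 1 array per tumour, a difference between tumours had no replicate check and received no p-value, and the number of arrays limited the precision of every value. Levels below are log2(intensity + 50) after quantile normalization, and fold differences refer to that scale, which understates the differences of dim genes.

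Among the genes named beforehand, the simple-epithelium keratins, Mki67, Erbb2 and Myc differed little between the tumours. Krt8 and Krt18 measured 12.40 ± 0.24 and 12.64 ± 0.13 (SD, n = 3), and the proliferation marker Mki67 measured 11.33 ± 0.21. Erbb2, a receptor tyrosine kinase, measured 8.70 ± 0.15 and Myc 10.07 ± 0.18. The oestrogen receptor gene Esr1 and the progesterone receptor gene Pgr had intensities of at most 16 and 8 in any tumour, below the low-signal floor. Wap, whose promoter drives the transgene, was also below the floor, with intensities of 88, 19 and 29 in tumours 1, 2 and 3. The casein gene Csn2 measured 10.62 ± 0.29. The retinoblastoma gene Rb1 measured 9.58 ± 0.44. Several cell-cycle genes differed more between tumours. Ccnd1, which encodes cyclin D1, was at 8.70, 10.74 and 9.63 in tumours 1, 2 and 3, a 4.11-fold range. The cell-cycle inhibitor gene Cdkn1a measured 9.91 ± 1.22, lowest in tumour 1, and the inhibitor gene Cdkn2a was at 7.39, 9.53 and 8.70. Krt14, a basal keratin, was below the floor on average, with intensities of 358, 59 and 50.

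Each tumour had its own set of genes that stood apart from both other tumours. Tumour 1 was at least 2-fold above both others for 87 genes and below both for 76. Tumour 2 was above both for 157 genes and below both for 86. Tumour 3 was above both for 112 genes and below both for 334, the most in these 6 counts. The counts were made among 6952 genes that passed the low-signal filter. That filter used a mean that includes the raised tumour, so some genes entered the counts above both others only through it. Comp, Cxcl11 and Rerg, named below, are examples. With placed genes kept by the mean of the other tumours, the counts above both were 61, 122 and 89 in tumours 1, 2 and 3. The counts below both were not remade in that way.

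In tumour 1 the widest gaps above the next tumour were those of Cxcl11 (21.8-fold), Met (19.9-fold), St7 (15.5-fold), Clec2d (12.8-fold) and Cxcl10 (11.1-fold). Cxcl10 and Cxcl11 are chemokines induced by interferon, and Met encodes the hepatocyte growth factor receptor. Met had an intensity of 4661 in tumour 1, 45 in tumour 2 and 185 in tumour 3. The widest gaps below belonged to Sema3b (6.27-fold), the cell-cycle inhibitor gene Cdkn2b (6.24-fold), the neurotrophin receptor gene Ntrk2 (5.40-fold), Armcx2 (5.40-fold) and Fbxo2 (4.78-fold).

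In tumour 2 the cartilage matrix gene Comp was 51.3-fold above the next tumour, with an intensity of 5811 against 69 and 36. It was followed by the metalloprotease gene Adamdec1 (11.9-fold), Ecrg4 (9.95-fold), the chitinase-like gene Chil3 (8.52-fold) and the tetraspanin gene Tspan2 (8.13-fold). Wfdc18 was 6.19-fold below both others, the transcription factor gene Sox2 5.03-fold, the lipogenic gene Thrsp 4.06-fold, Bex1 3.45-fold and Tomm7, of the mitochondrial import machinery, 3.27-fold.

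In tumour 3 the Ras-like gene Rerg was 37.3-fold above the next tumour, and the organic anion transporter gene Slco1b2 24.5-fold. Plekha5 was 19.1-fold above, the phosphodiesterase subunit gene Pde6h 12.9-fold and the deoxyribose-phosphate aldolase gene Dera 12.3-fold. Rerg had intensities of 25 and 25 in tumours 1 and 2 and 2992 in tumour 3. The mucin gene Muc1 was 11.7-fold below both others, BC018473 8.22-fold, the interferon-induced gene Usp18 8.02-fold, the aminopeptidase gene Anpep 6.59-fold and the ceruloplasmin gene Cp 6.53-fold. All 6 other probe sets of Cp had the same direction. The gap of BC018473 rested on a suffixed probe set (with a letter, here a, before the ending of its ID). With such probe sets left out its highest and lowest tumours differed by 0.33 (log2).

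**Figure D1:**
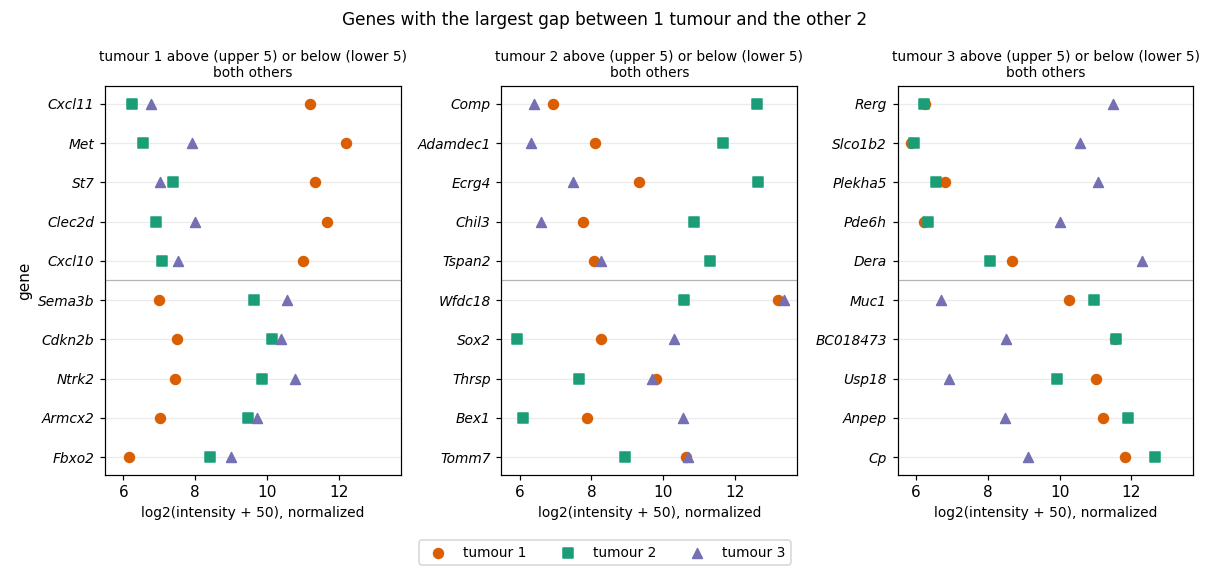
Normalized log2(intensity + 50) of the 30 genes with the widest gap between 1 tumour and both others, 5 above and 5 below for each tumour, with 1 point per tumour. The horizontal axis is the log2 level and each line is a gene; Comp in tumour 2 (51.3-fold) and Rerg in tumour 3 (37.3-fold) lie farthest from the other tumours.

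Across all 6952 genes, tumours 1 and 2 were the most alike pair and tumours 2 and 3 the least alike. Tumour 1 had 256 genes at least 2-fold higher than in tumour 2, and tumour 2 had 318 higher than in tumour 1, together 8.26% of genes. Between tumours 1 and 3 the counts were 579 and 316 (12.9%), and between tumours 2 and 3 they were 749 and 357 (15.9%), the larger count in each case being genes lower in tumour 3. Pearson's r across genes was 0.880 for tumours 1 and 2, 0.830 for tumours 1 and 3 and 0.813 for tumours 2 and 3, and the SD of the log2 difference was 0.61, 0.73 and 0.77. Genes are not independent replicates, so these values describe the arrays. Highest and lowest tumour differed at least 2-fold for 1723 genes (24.8%), at least 4-fold for 238 (3.42%) and at least 8-fold for 59. The median gene had a range of 0.66 (log2), or 1.58-fold, and an SD of 0.34.

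Genes of the interferon response and of antigen presentation differed together and most widely among the lists fixed beforehand. Their median range was 2.82 (log2), 21 of the 22 genes past the filter differed at least 2-fold, 20 were highest in tumour 1 and 19 were lowest in tumour 3. The antiviral gene Rsad2 was at 12.23, 8.79 and 6.79 in tumours 1, 2 and 3, a 43.4-fold range. The interferon-inducible GTPase gene Igtp had a 20.6-fold range, from 11.80 in tumour 1 to 7.43 in tumour 3. Usp18 and Ifit1 had ranges of 17.1-fold and 13.8-fold. The GTPase gene Gbp2 was at 11.39, 8.93 and 7.58 and the antiviral gene Mx1 at 9.56, 7.31 and 6.10. Mx1 passed the filter only through tumour 1. B2m, the light chain of class I histocompatibility molecules, differed least, at 13.04, 13.03 and 12.06. The list's shift from the mean of the tumours was 1.32 in tumour 1, -0.22 in tumour 2 and -1.37 in tumour 3, all outside the central 95% of 10000 random lists matched on mean level. In tumour 2 the shift had the opposite sign, 0.15, when only genes above the 75th percentile were kept. Macrophage genes were also lowest in tumour 3.

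Markers of macrophages and of fibroblasts with their extracellular matrix were lower in tumour 3. Of the 19 macrophage genes past the filter, 19 were lowest in tumour 3 and 12 differed at least 2-fold. The complement gene C1qc was at 11.62, 11.10 and 9.82, the mannose receptor gene Mrc1 at 8.73, 10.24 and 8.62, and Cd14, which differed least, at 11.72, 11.79 and 11.58. With array medians subtracted the difference of Cd14 was 0.00 (log2). The macrophage list shifted by 0.32, 0.25 and -0.66 in tumours 1, 2 and 3. In the fibroblast and matrix list 15 of 20 genes were lowest in tumour 3, 15 were highest in tumour 2, and 12 differed at least 2-fold. The matrix gene Thbs2 was at 10.39, 9.40 and 7.95, fibronectin (Fn1) at 11.33, 13.10 and 11.84, and the proteoglycan gene Dcn at 9.73, 10.06 and 9.77. That list shifted by 0.24, 0.38 and -0.53. Endothelial genes had the same order, with 6 of 6 lowest in tumour 3 and shifts of 0.05, 0.44 and -0.39, of which only that of tumour 2 was outside the central 95% of random lists. Among endothelial genes Cdh5 had a 2.57-fold range, Esam 2.27-fold and Eng 1.34-fold. The spread of the endothelial list lay at percentile 76.8 of random lists.

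Adipocyte genes had the opposite pattern. Of 6 genes past the filter, 5 were highest in tumour 3 and 5 differed at least 2-fold, with shifts of -0.59, -0.57 and 1.38. The fatty acid binding protein gene Fabp4 was at 8.93, 8.41 and 11.41, and the carbonic anhydrase gene Car3 at 8.56, 9.18 and 11.25. The transcription factor gene Cebpa differed least and ran the other way, at 10.10, 9.56 and 9.13. The Fabp4 value rested on a suffixed probe set, and without such probe sets its range was 0.19 (log2). Adipoq, with intensities of 66, 94 and 678, passed the filter only through tumour 3. The wide spread of these cell-type lists rested on tumour 3. Between tumours 1 and 2 alone, the spread lay at percentile 84.0 of random lists for adipocyte genes, 87.2 for fibroblast genes and 92.4 for macrophage genes. Control probe sets for 18S ribosomal RNA also differed on the tumour 3 array (24.0-fold dimmer for the middle part, 8.89-fold dimmer for the 5′ part and 3.16-fold brighter for the 3′ part), and differences of RNA or preparation were not separated from any result for tumour 3.

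Among epithelial lists, most milk and lactation genes past the filter were highest in tumour 1, and 4 of 6 basal genes past it were highest in tumour 2. Of 10 lactation genes past the filter, 8 differed at least 2-fold and 6 were highest in tumour 1, with shifts of 0.61, -0.15 and -0.59. The spread of that list lay at percentile 96.5 of random lists without tumour 1. The butyrophilin gene Btn1a1, of the milk fat globule, was at 9.99, 6.79 and 6.87, and the folate receptor gene Folr1 at 10.22, 8.92 and 7.26. Btn1a1 passed the filter only through tumour 1. The casein gene Csn3 differed least, at 13.41, 13.18 and 13.41, tied between tumours 1 and 3. Its range moved to 0.81 (log2) with the mean of probe sets and 0.39 with array medians subtracted, and its intensities (11104, 8964 and 10114) lay near the array maxima of 11344, 11659 and 10789. The 3 other genes not highest in tumour 1 were also caseins: Csn1s1 (highest in tumour 3, 2.31-fold above tumour 2), Csn1s2a (8.29, 8.51 and 9.45) and Csn2 (10.29, 10.84 and 10.73). Without suffixed probe sets the difference of Btn1a1 was 0.72 (log2). In the basal and myoepithelial list 4 of the 6 genes past the filter differed at least 2-fold, with shifts of -0.15, 0.57 and -0.66. The other 8 genes were below the floor, among them the basal keratins Krt5, Krt14 and Krt17, which were brightest in tumour 1. The laminin genes Lamb3 and Lama3 had ranges of 6.68-fold and 4.41-fold, and Acta2 had one of 1.51-fold. Lama3, highest in tumour 2, passed the filter only through that tumour. The sign of the Acta2 difference turned (-0.23, log2) without suffixed probe sets. The luminal list was spread less, at percentile 96.0 of random lists, and none of its shifts (0.14, 0.10 and -0.21) was outside the central 95%. That percentile was 98.1 with no low-signal filter and 97.9 with the mean of probe sets, both outside the central 95%. Within it Muc1 was at 10.26, 10.96 and 6.71 and the tight-junction gene Cldn4 at 10.89, 9.44 and 7.34, while the transcription factor gene Elf3 was at 9.30, 9.29 and 9.34. The spread of basal genes was at percentile 90.7 between tumours 1 and 3 alone, 94.2 with an offset of 16 and 96.8 with no low-signal filter.

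Targets of the transcription factor p53, which respond to DNA damage, were lowest in tumour 1 and highest in tumour 2. Of 13 p53 targets past the filter, 10 were lowest in tumour 1, 10 were highest in tumour 2 and 8 differed at least 2-fold. Cdkn1a had a 5.37-fold range, with intensities of 330, 1992 and 1085. The growth-arrest gene Gadd45a was at 7.43, 9.58 and 9.78, and Mdm2, a ubiquitin ligase gene, was at 8.57, 10.21 and 9.17. Pmaip1 differed least, at 7.23, 7.31 and 7.70. The list shifted by -0.48, 0.65 and 0.09. With tumour 1 or tumour 2 left out, its spread lay at percentiles 95.1 and 95.8 of random lists.

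Of the imprinted genes, which are expressed from 1 parental allele, most of those past the filter were lowest in tumour 3. Of 8 genes past the filter, 7 were lowest in tumour 3, 5 were highest in tumour 2 and 7 differed at least 2-fold, with shifts of 0.11, 0.64 and -0.93. The growth factor gene Igf2 was at 9.17, 6.62 and 6.44, with tumour 1 5.86-fold above the next tumour, and passed the filter only through tumour 1. The zinc finger gene Plagl1 was the exception past the filter, highest in tumour 3 (9.57) and lowest in tumour 1, with a 2.98-fold range. Below the floor, Sgce (intensities of 29, 28 and 193), Mest (67, 113 and 155) and Dlk1 were also brightest in tumour 3. The dim genes Meg3, Ndn, Peg10 and Zim1 were not. The cell-cycle inhibitor gene Cdkn1c was at 7.40, 8.87 and 6.23 and passed the filter only through tumour 2. Gnas, which differed least, was at 12.29, 12.36 and 11.67. With suffixed probe sets left out, that difference of Gnas had the opposite sign (-0.27, log2).

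**Figure D2:**
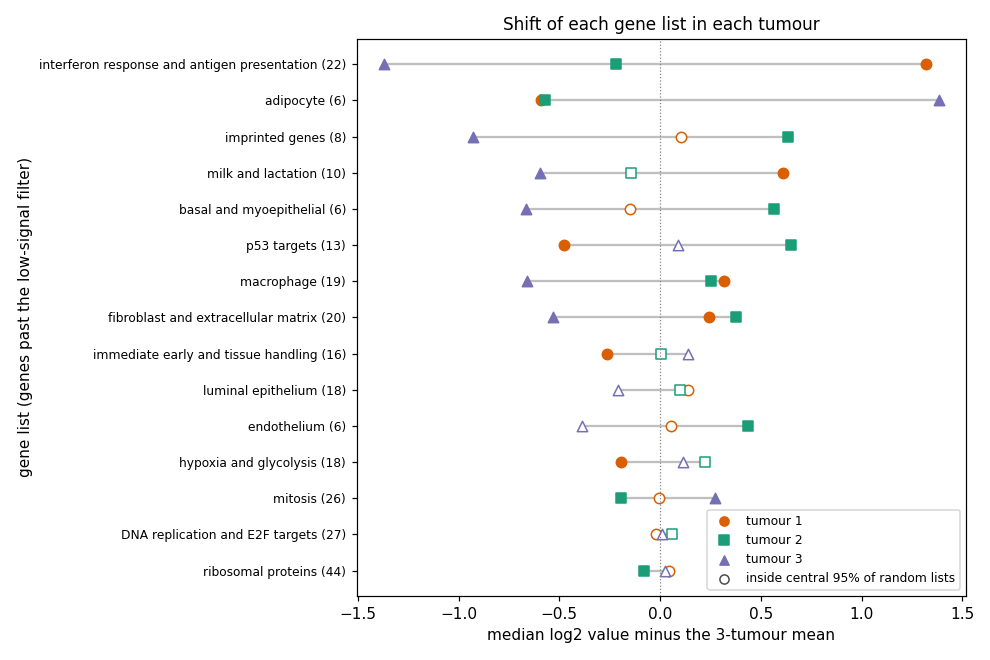
Median log2 level of each gene list relative to the mean of the 3 tumours (horizontal axis), with 1 symbol per tumour and the number of genes past the filter in brackets. Filled symbols lie outside the central 95% of 10000 random lists; the interferon list runs from -1.37 in tumour 3 to 1.32 in tumour 1, and the ribosomal list lies within -0.08 to 0.05.

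Genes of DNA replication and of ribosomes differed little between tumours. Of 27 replication genes past the filter 4 differed at least 2-fold, the list's spread lay at percentile 12.1, and its shifts were -0.02, 0.06 and 0.01, where that of tumour 2 was -0.03 with array medians subtracted. The shift of tumour 3 was 0.22 with the mean of probe sets and 0.14 without suffixed ones. Between tumours 1 and 2 alone the spread lay at percentile 1.19. The cyclin gene Ccne2 had the widest range (3.64-fold), followed by the flap endonuclease gene Fen1 (2.44-fold), and the polymerase subunit gene Pola2 differed 1.03-fold. Mitosis genes were spread at percentile 26.3, yet 15 of 26 were highest in tumour 3 and 15 lowest in tumour 2, with shifts of 0.00, -0.19 and 0.27, and those of tumours 2 and 3 were outside the central 95%. Racgap1 and Cdc20 had ranges of 2.48-fold and 2.20-fold, and Ttk differed 1.13-fold. Ribosomal protein genes had a median range of 0.35 (log2), below every random list. The ribosomal shift of tumour 2 (-0.08) was nonetheless outside the central 95%, and with array medians subtracted the shifts of tumours 2 and 3 were -0.19 and 0.09 in place of -0.08 and 0.03. Rpl22 differed 3.50-fold and Rpl22l1 2.88-fold, whereas Rpl7 differed 1.01-fold. A second probe set of Rpl22 did not repeat its direction. Without suffixed probe sets the ribosomal list's spread was at percentile 36.8, and between tumours 1 and 2 alone it was at 12.1.

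Hypoxia and glycolysis genes were lowest in tumour 1 for 10 of 18 genes past the filter. Of these 18 genes 5 differed at least 2-fold, and the list's spread lay at percentile 55.05 of random lists, inside the central 95%. The angiogenic factor gene Vegfa was at 8.35, 9.22 and 9.95 and the glucose transporter gene Slc2a1 at 9.77, 10.92 and 11.31, while Pgam1 differed 1.30-fold. Without suffixed probe sets the range of Slc2a1 was 0.72 (log2). The shifts were -0.19, 0.22 and 0.11, and that of tumour 1 was outside the central 95%. Immediate early genes, which respond to tissue handling, were lowest in tumour 1 for 10 of 16 genes, with shifts of -0.26, 0.00 and 0.14, where that of tumour 2 changed sign with the scaling, and 8 differed at least 2-fold. Klf4 was at 7.31, 7.88 and 9.57, the heat shock gene Hspa1a at 7.54, 8.51 and 9.46, and Ier2 at 10.79, 10.76 and 10.73. The spread of the immediate early list was at percentile 83.7 without tumour 1 and 80.8 without tumour 3.

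Over all ranked lists, 9 of 15 had a spread above the central 95% of random lists, 1 had a spread below it, and 26 of 45 shifts were outside the central 95%. The shifts of a list are deviations from the mean of the same tumours. They are therefore not separate outcomes, and their count overlaps with that of the spreads. The other 7 lists had too few genes past the filter to rank. Among neuroendocrine genes only Cpe passed, at 11.77 ± 0.46, and among T and NK cell genes only Thy1, at 8.94 ± 0.66, which fibroblasts also express. B and plasma cell genes were represented by Ighm (8.22 ± 0.05) and Jchain (7.76 ± 0.13), and skeletal muscle genes by Acta1 (7.47 ± 1.01) and Mb (7.61 ± 0.61). The narrow range of Ighm depended on its probe set, as it was 0.56 (log2) with the mean of probe sets and -0.11 without suffixed ones. The 4 neutrophil and myeloid genes past the filter were highest in tumour 2 and lowest in tumour 3. Among these S100a8 was at 9.21, 10.39 and 7.81, S100a9 at 8.65, 10.05 and 7.59, Il1b at 7.56, 8.61 and 7.23, and Prtn3 at 8.16, 8.21 and 6.69. No erythroid gene passed the filter. Xist, the RNA that silences the inactive X chromosome, was at 12.19 and 12.16 in tumours 1 and 2 and at 10.07 in tumour 3, 4.25-fold lower, and its 2 other probe sets had the same direction.

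The direction of differences between tumours mostly recurred in a second probe set of the same gene. For 2396 genes with at least 2 probe sets past the filter, the log2 differences by both probe sets correlated across genes with r = 0.678 for tumours 1 and 2, 0.641 for tumours 1 and 3 and 0.619 for tumours 2 and 3, against -0.02, -0.01 and 0.03 for probe sets paired at random. Of the genes at least 2-fold apart by the brighter probe set, 169 of 175 (96.6%) had the same sign in the other between tumours 1 and 2. The count was 264 of 287 (92.0%) between tumours 1 and 3 and 343 of 384 (89.3%) between tumours 2 and 3, where random pairing gave 44.0%, 45.6% and 50.8%. The second probe set also reached 2-fold for 89 of 175, 127 of 287 and 161 of 384. Among the named genes 28 had another probe set past the filter, and for 26 of them all others had the same direction. The exceptions were Rpl22 and Rpl7. Both probe sets measured the same labelled RNA, so this repeats the measurement and not the tumour.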

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

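All tests in this part were chosen after the result was seen.

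Control probe sets, which entered no gene result, differed in tumour 3 as deposited. Those for the middle and the 5′ part of 18S ribosomal RNA were 24.0-fold and 8.89-fold dimmer in tumour 3 than the mean of tumours 1 and 2, and the 3′ one was 3.16-fold brighter. Control probe sets for the repeat elements B1 and B2 were 2.67-fold and, for the dimmer of the B2 probe sets, 3.32-fold brighter in tumour 3. The other B2 probe set was 1.43-fold brighter there. By contrast, the 27 probe sets for bacterial transcripts that had no signal were at or below an intensity of 18 in every tumour. With 3 samples no sample could be tested as standing apart from its group.

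Of the explanations for the 18S pattern, a lower amount of 18S RNA in the labelled sample would dim every 18S probe set, and the 3′ probe set was 3.16-fold brighter. Shorter labelled products would dim the 5′ and middle probe sets as seen, and would lower the 5′ over 3′ ratio of control transcripts. Of the 2 control transcripts above the low-signal floor at both ends, 1 had its highest ratio in tumour 3 (Gapdh, 1.24 against 1.11 and 0.825), and Actb had its lowest there (0.794 against 0.962 and 0.828). Gapdh and Actb lie near the top of the arrays' range, where ratios may be compressed. The dimmer control transcripts also had their highest ratio in tumour 3 (Tfrc 0.348 against 0.131 and 0.231, Pcx 0.562 against 0.209 and 0.247). Their 5′ probe sets lay below the floor in some or all tumours, so shorter products stay open. A preparation that differed between the title numbers cannot be told apart from the tumour, because tumour 3 alone carried its number; r between tumours 1 and 2 exceeded the next r by 0.0499. No biological explanation was tested.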

How the results depend on the processing

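No paired analysis was possible because all samples form 1 group. The longest run of neighbouring genes was tested under alternatives chosen after seeing the data. Of the alternative values of the summaries 209 stayed close to the reported ones and 67 moved. For lists 531 stayed, 29 moved and 1 reversed, for single genes 726 stayed and 35 moved, and for runs 13 stayed and 2 moved. A count stayed if it changed at most 1.5-fold, and a list's spread if it remained inside, above or below the central 95%. A single gene's difference stayed if it changed by no more than the gene's SD over the tumours. List shifts were held to the SD of the list's own shifts. Widely spread genes and lists could therefore hardly move, so the shares that stayed are no measure of robustness. Using the values as deposited or subtracting array medians moved no summary beyond its limits; as deposited, 200 genes were higher in tumour 1 than in tumour 2 and 377 the other way.

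With an offset of 150, which shrinks differences of dim genes, the SD of the log2 difference was 0.51 for tumours 1 and 2, 0.60 for tumours 1 and 3 and 0.64 for tumours 2 and 3. The genes at least 2-fold higher then numbered 147 in tumour 1 and 183 in tumour 2, 335 in tumour 1 and 193 in tumour 3, and 461 in tumour 2 and 220 in tumour 3. Genes at least 2-fold apart between highest and lowest tumour were 1064. Tumour 1 was below both others for 33, tumour 2 above for 93 and below for 39, and tumour 3 below for 175.

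With no low-signal filter r was 0.956, 0.936 and 0.930 for the same pairs and the SD of the difference 0.52, 0.62 and 0.65. Tumour 3 was above both others for 169 genes. Probe sets of the same gene then correlated with r of 0.575, 0.594 and 0.534, and had the same sign in 89.0% (tumours 1 and 2) and 84.4% (tumours 2 and 3). The median SD of listed genes was 0.36.

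With the filter at the 75th percentile, where fewer genes remain, r was 0.813, 0.737 and 0.706. The pair counts were 150 and 156, 297 and 160, and 412 and 208, and 924 genes were at least 2-fold apart. Tumour 1 was above both others for 38 genes and below for 41, tumour 2 above for 71, and tumour 3 above for 52 and below for 196. The r of probe sets was 0.663 for tumours 2 and 3. The interferon list's shift in tumour 2 reversed from -0.22 to 0.15, and the cause was not tested.

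With the mean of probe sets 494 genes were higher in tumour 2 than in tumour 3, and tumour 1 was below both others for 43. Without suffixed probe sets the r of probe sets was 0.603 for tumours 1 and 2 and 0.530 for tumours 2 and 3. In that setting the same sign held in 82.0% for tumours 2 and 3, and 0 lists were spread less than the 2.5th percentile. The cause was not tested. A threshold of 1.5-fold counted 3971 genes apart between highest and lowest tumour and 4-fold counted 238.

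Leaving out each tumour in turn, which leaves 1 pair, gave 591 to 1100 genes at least 2-fold apart, fewest without tumour 3. The genes above the remaining tumour were 261 to 555 for tumour 1, 330 to 729 for tumour 2 and 339 to 371 for tumour 3, and those below were 330 to 339, 261 to 371 and 555 to 729. The median SD of listed genes was 0.30 to 0.44.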

Other observations

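All tests and gene lists in this part were chosen after the data were seen.

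Class II histocompatibility genes, which present antigen on macrophages, dendritic cells and B cells, followed another order than the interferon list. All 5 genes past the filter (H2-Aa, H2-Ab1, H2-Eb1, H2-DMa and Cd74) were highest in tumour 2 and lowest in tumour 3, with list shifts of 0.18, 1.12 and -1.46 in tumours 1, 2 and 3. Cd74, the invariant chain, was at 11.75, 12.45 and 9.55, a 7.49-fold range, and H2-Ab1 had a 6.93-fold range. Most genes of the mitochondrial ribosome and of the respiratory chain were lowest in tumour 2. Of 71 genes of the mitochondrial ribosome 66 were lowest there. Of 66 respiratory chain genes 51 were lowest and 6 highest in tumour 2. The shifts of these lists in tumour 2 were -0.45 and -0.39. As deposited these shifts were -0.40 and -0.43. Cholesterol synthesis genes were lowest in tumour 2 for 9 of 9, with a shift of -0.37, and Cyp51 had a 4.27-fold range from 7.51 in tumour 2 to 9.60 in tumour 3.

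Some genes of brown fat were brighter in tumour 3 than in the other tumours. Ucp1, the uncoupling protein of brown fat, had intensities of 3, 12 and 687 in tumours 1, 2 and 3, Cox8b 20, 3 and 379, Cidea 13, 63 and 367, and Cox7a1 55, 32 and 182. Elovl3 stayed dim, at 19, 15 and 95. The deiodinase gene Dio2 had no such order, at 35, 53 and 36. Ppargc1a, the only gene of the 7 that passed the filter, had similar intensities in tumours 2 and 3 (36, 199 and 221). With 1 such gene the list was not ranked.

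Several of the genes that stood apart lie next to each other in the RefSeq gene order of assembly GRCm38.p6. In tumour 2 the neighbours Gdap2, Man1a2, Vangl1, Tspan2, Sike1 and Nras, 6 in a row among genes past the filter, were 4.57-fold to 8.13-fold above both others, while the flanking genes Tbx15 and Bcas2 were not (0.09 and -1.12, log2). In tumour 3, runs of 5 (Emp1, Atf7ip, Plbd1, H2aj and Wbp11) and 3 (Plekha5, Aebp2 and Slco1b2) lay in a span from Emp1 to Slco1b2 where 12 of 16 genes past the filter were at least 2-fold above both others, among them Rerg, Dera and Pde6h. That share is inflated, because Rerg, Pde6h, Plekha5 and Slco1b2 pass the filter only through their level in tumour 3; with genes kept by the mean of the other tumours it was 8 of 12. The chromosome holding that span had 24 of the 111 placed genes of this kind, where an even spread gives 5.83. Of these 24, 12 were those of the span itself, and the count used the same inflating filter. In tumour 1, Met, Capza2 and St7 formed a run of 3, a length that 16 of 1000 shuffled gene orders reached, and the other runs of 3 were interferon-induced clusters such as Cxcl9, Cxcl10 and Cxcl11.

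Chance placement along the chromosomes would give runs as long in shuffled gene orders, and 0 of 1000 orders did for tumour 2 and 0 of 1000 for tumour 3, with a longest run of 4. With genes kept by the mean of the other tumours the runs of 6 and 5 remained and again 0 of 1000 orders reached them, whereas Met and St7 fell below that filter. Sequence variants under the probes would act on single probe sets. Of the other probe sets of these genes past the filter, 13 of 13 were also at least 2-fold above both other tumours. The filter used a mean that includes the raised tumour. Dim probe sets that were not raised would have been left out, so this count cannot decide on sequence variants. A candidate explanation is more copies of these regions in the tumour cells, as a hypothesis. Low-signal genes inside the spans did not settle it, since they lie near the floor and the filter itself selects them for a low level. In the tumour 2 span 5 of 6 were above both other tumours, and in the tumour 3 span 4 of 11. Of the 4 genes of the tumour 3 span past the filter that stayed under 2-fold, Mgp (1.95-fold) and Eps8 (1.79-fold) were above both others. The 2 other probe sets of Eps8 were more than 2-fold above both (1.14 and 1.32, log2). Arhgdib was not raised (9.39 against 9.32 and 9.45) and Mgst1 was lower (11.84 against 12.33 and 12.29). DNA was not measured. With no low-signal filter dim genes interrupt the rows of neighbours, and the longest run anywhere was 3 in both tumours. Inside the tumour 2 span no 3 neighbours then stood together, so its run of 6 was not kept under that setting.

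Interferon genes were high in tumour 1 and low in tumour 3. Array scaling is argued against, as the list's median difference between these tumours was at least 2.78 (log2) under all 3 scalings. More macrophages in tumour 1 would raise macrophage genes alike, but against tumour 2 these differed by -0.063 (quartiles -0.23 and 0.50) where the interferon list differed by 1.38. Against tumour 3 macrophage genes were higher by 0.98 and interferon genes by 2.82, so a share from macrophages stays open there. Infection, other immune cells and tumour-cell signalling were not tested.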
